A study of Mus musculus with 3 samples.

How the data were processed

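The series holds wild-type C57BL/6 mouse bone marrow cells that the labels call modified GMP, where GMP is the usual short form for granulocyte-monocyte progenitor. CITE-seq was used, in which transcripts and antibody-bound DNA tags (ADT) are counted in the same cells. Per the labels' protocols, marrow from crushed hindlimbs was enriched with CD117 microbeads, stained with tagged and fluorescent antibodies and sorted, and 10000 cells per sample were loaded on the 10x Genomics 3' v2 assay. Per the labels, 1 male and 1 female mRNA library were sequenced to 689 M and 676 M reads, and the antibody library pooled both sexes. The sequenced pool held 90% mRNA library and 10% antibody library. The submitters' processing notes name Cell Ranger 2.1.0 and the genome build mm10. The gene annotation, cell calling, clustering method and doublet removal are not given in the sources used here.

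The authors deposited a table of raw UMI counts for 28692 gene IDs in 11132 cells, a cluster name for each cell, and 4 antibody values per cell on 2 scales. The library of each cell was read from the ending of its name, which marks the male or the female library. Symbols were found for 28339 IDs, and the 353 IDs without one held 0.0230% of the UMIs. The deposited antibody counts are whole numbers, and removal of duplicate reads is not stated for them. The deposited antibody values on a natural log scale are named as a centred log ratio. All 44528 of them equalled the natural log of (count + 1) over (sum of the 4 counts + 1) within 1e-08, so they are log shares within the cell and are not centred. The cluster names are the authors' own, and what they abbreviate is not given in the sources used here.

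Cells passed no further filter here. The lowest UMI count of a cell was 4373, and no doublet caller was run. Cells were grouped by the authors' cluster names under a rule fixed before the data were examined. The Gran class was Gran-1 and Gran-2, the early class HSCP-1, HSCP-2 and Multi-Lin, and the monocytic class Mono, MDP and cMoP. Meg, Eryth, DC, MP and IG2 fell in no class, and the Myelo clusters fell in none of these. UMI counts were summed per library and class, because cells are not replicates. The male and the female library were taken as 2 wild-type replicates. Nothing in the labels says how many mice each library came from, so p-values do not measure a spread between mice. With the library as a covariate, they rest on how alike the class difference was in these 2 libraries. They also rest on values shared between genes.

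The sums were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, the library as a covariate, 4 sums and 1 residual degree of freedom). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change over the square root of F. CPM values beside a fold change are scaled by the TMM factors of that fit, and CPM values of clusters or whole libraries are not. The procedure was tested on simulated counts with 200 changed genes. For Gran against early, it recovered 68.2% of changes of 0.5, 85.1% of 1 and 97.0% of 2 on the log2 scale, with 8 false calls among 11851 unchanged genes. For Gran against monocytic the recovered shares were 66.7%, 83.6% and 97.0%, with 11 false calls among 11402. For Myelo against Gran they were 53.0%, 88.1% and 98.5%, with 3 false calls among 11273. All simulated genes of a comparison had 1 common spread and the same relative level in both libraries. The real sums differ in this, and far more than 200 genes passed in them. The rate of false calls in the real data therefore cannot be read from the simulation. Clusters were made from RNA by the authors, so gene counts describe the clusters and are not independent evidence of them.

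The genes named were chosen by a rule fixed before the data were examined. It takes up to 4 members of each of 5 lists (primary granule, secondary granule, neutrophil regulators, monocyte, multipotent) by mean CPM, and Gfi1, Irf8, Cebpe, Cebpa and Csf1r always. It adds 2 members of each other list with 3 or more members past the threshold. It also adds the 5 largest changes each way among genes with a mean CPM of 50 or more and the same sign in both libraries. Besides 1 gene not reported here, this gave 49 genes for Gran against early, 47 for Gran against monocytic and 48 for Myelo against Gran, of which the text names a part. List medians were ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Of 212 list genes, 1 (Cebpd) was not in the count table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and DESeq2 1.42.0 were also used. Gene coordinates are those of the mouse assembly GRCm38.p6, the same build as mm10, matched by symbol.

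Shares of cells carry exact Clopper-Pearson 95% intervals, and CPM values of a whole library exact Poisson 95% intervals. Both cover counting error only. Female and male libraries were not tested against each other, since there was 1 per sex. Relations of antibody to transcript are Spearman's rho across cells within each library, given without p-values. Total UMIs were 91448433 in the female and 124967351 in the male library, with medians of 21202 and 18687 per cell. Alternatives fixed before the data were examined were another scaling (relative log expression), no filter on low counts, DESeq2, no library term, cells thinned to 5000 UMIs, omission of the 2% of cells with the most UMIs, and a fit over the 12 clusters with 50 cells per library. That fit averages the clusters of a class and leaves out HSCP-1, Eryth, DC, cMoP and Myelo-4, so it changes several choices together. Cells under 5000 UMIs, 19 female and 118 male, were left out of the thinned data. Each library alone for the genes, other antibody scales and equal weight per cluster were also planned. Settings added after seeing the data were Gran-2 alone, the Myelo clusters joined to Gran, median antibody counts, each library alone for the antibodies, log shares in the antibody correlations, and the comparison of Myelo with Gran.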

Results

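Bone marrow progenitors of wild-type mice were profiled for transcripts and for 4 surface proteins in the same cells. After the authors' processing, 4336 cells came from the female and 6796 from the male library. Total UMI counts were 91448433 (female) and 124967351 (male). The median cell held 3787 detected genes in the female and 3483 in the male library. Antibody counts had medians of 5518 and 3785.5 per cell. Each sex was 1 mRNA library, and values across both libraries are given as mean ± SD (n = 2). Antibody tags of both sexes were sequenced as 1 pooled library, and antibody values were split by the mRNA library of the cell.

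Cells of the granulocyte branch took the largest share among 4 groups of clusters in both libraries. Gran-1 and Gran-2 together made up 27.4% of female cells (95% interval 26.1% to 28.7%, exact binomial) and 31.5% of male cells (30.4% to 32.6%). Myelo-1 to Myelo-4 added 22.9% and 19.1%. The early clusters HSCP-1, HSCP-2 and Multi-Lin held 22.0% (20.8% to 23.3%) and 20.1% (19.2% to 21.1%), and the monocytic clusters Mono, MDP and cMoP held 13.6% (12.6% to 14.6%) and 12.3% (11.5% to 13.1%). Meg was 1.98% of female and 1.25% of male cells, Eryth 0.946% and 0.633%, and DC 0.254% and 0.324%. These shares describe CD117-enriched and sorted cells, not whole marrow, and no test between the sexes was possible.

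**Figure D1:**
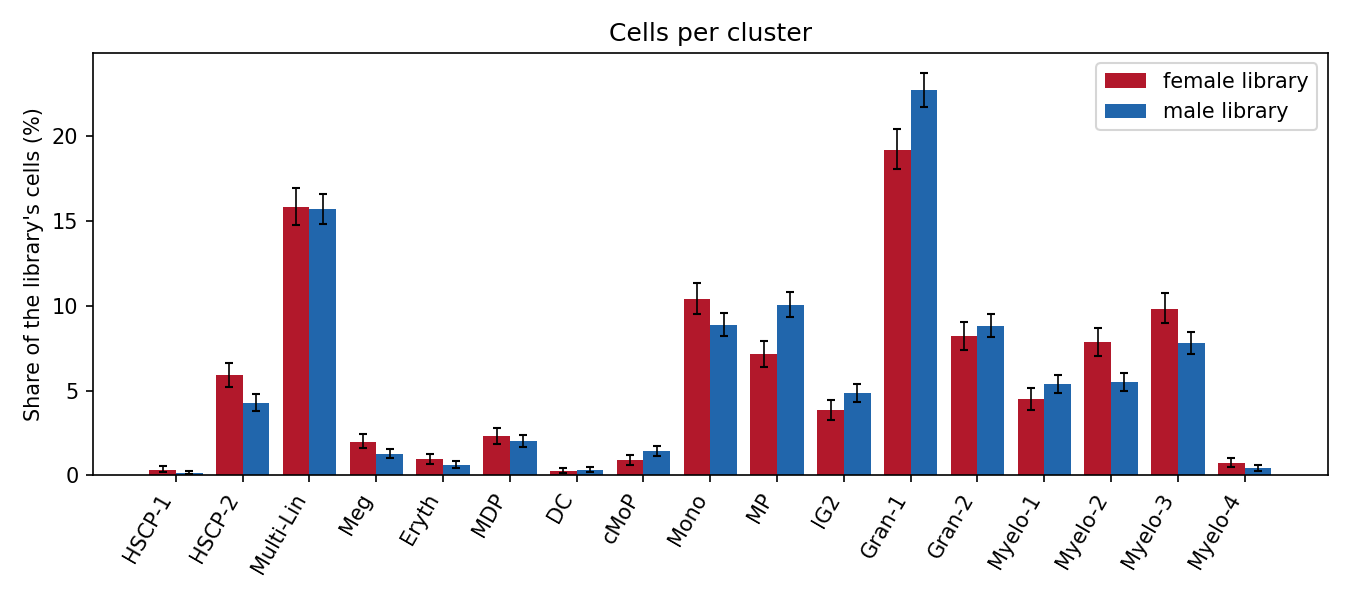
Share of each library's cells (percent, vertical axis) in each of the 17 clusters, female and male side by side, with exact binomial 95% intervals as error bars. Gran-1 was the largest cluster in both libraries, with 19.2% of female and 22.7% of male cells.

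The first comparison asked which transcripts differed between the Gran and the early clusters, in a series about the states that cells pass through in granulocyte specification. Primary granule genes were higher in Gran. Elane, which encodes neutrophil elastase, was 11.2-fold higher (17740 ± 1795 against 1586 ± 178 CPM), and Prtn3 and Ctsg, which encode serine proteases of the same granules, were 4.74-fold and 4.31-fold higher. The transcription factor genes Gfi1 and Cebpe, both required for neutrophil development, were 3.91-fold (88.6 ± 0.718 against 22.6 ± 0.0809 CPM) and 3.15-fold higher (333.2 ± 13.7 against 105.7 ± 7.04 CPM). Genes of stem and multipotent progenitors were lower in Gran: Sox4 was 9.47-fold and Cd34 5.82-fold lower.

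Of the 12 primary granule genes, 11 were higher and 1 was lower in Gran, with the same counts when adjusted over the list alone. Their median log2 fold change of 2.04 was at percentile 100 of the random lists. All 16 multipotent genes were lower (16 adjusted over the list alone), with a median of -3.24 at percentile 0. Adgrg1 (log2 fold change -3.06 ± 0.04, SE) and Cd27 (-1.61 ± 0.04) were among them. Of 11 neutrophil regulator genes tested, 6 were higher and 5 lower, also when adjusted over the list alone. Xbp1, a regulator of the unfolded protein response, rose by 0.95 ± 0.04 on the log2 scale, and Lmo4 fell by 2.11 with an SE of 0.04. Cebpa was near equal, at 108.6 ± 7.37 CPM in Gran and 123.9 ± 10.97 in early cells (log2 fold change -0.19, edgeR adjusted p = 0.000359). Irf8, a regulator of monocyte and dendritic fate, was 46.6 ± 2.71 against 55.5 ± 1.56 CPM (log2 fold change -0.25). Both depended on the setting: thinned to 5000 UMIs per cell, Cebpa (-0.13) and Irf8 (-0.19) did not pass. In the fit over 12 clusters, which changes the clusters included, their weight and the model together, both were positive, at 0.77 and 0.16.

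Of 18 secondary granule genes, 15 were higher in Gran, none was lower and 3 did not pass, the same as when adjusted over the list alone. The rise lay mainly in Gran-2, with a summed CPM of 37209 against 9088 in Gran-1. Most of the Gran-2 sum was S100a8, at 21190 (female) and 22225 (male) CPM, against 4243 and 4105 in Gran-1. The ratios of Camp and Ngp to S100a8 were lower in Gran-2 than in Gran-1 in both libraries. The sum therefore does not show that the other members rose alike. The summed CPM of the list was 6046 to 6446 in the early clusters. DC (9548) and cMoP (9827) were above Gran-1 in the mean, but DC only in the male library. There it had 10160 against 8296, and in the female library 8937 against 9879. S100a8 was lower in DC (2992 female, 2217 male) and cMoP (2918, 2179) than in Gran-1, so it does not account for their higher sums. S100a8 and S100a9, subunits of calprotectin, were 4.58-fold and 2.99-fold higher. Camp and Ngp were 1.63-fold and 1.42-fold higher, and Ngp did not pass without the library term. S100a8, S100a9, Camp and Ngp were also counted in clusters of other lineages, at means of 2492, 1791, 774.2 and 598.04 CPM over the early, Meg, Eryth and MDP clusters. The monocyte list was mixed, with 4 of 16 genes higher, 8 lower and 4 not passing (5 and 8 adjusted over the list alone). Ly6c2, a Ly-6C gene, was 16.1-fold higher in Gran (3193 ± 163 against 199 ± 8.18 CPM), while S100a10 was 4.29-fold lower. Csf1r, the receptor gene of the monocyte growth factor CSF-1, did not pass (5.35 ± 0.203 against 5.78 ± 0.712 CPM, edgeR adjusted p = 0.4998). It was lower with Gran-2 as the only Gran cluster (log2 fold change -0.64) and higher in the fit over 12 clusters (0.94).

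Genes of other lineages were mostly lower in Gran than in the early clusters. Of 12 eosinophil, basophil and mast cell genes, 11 were lower and 1 higher. The summed CPM of this list was 2093 in Multi-Lin, but 74.7 in HSCP-1 and 238 in HSCP-2. Gran-1 (367) and Gran-2 (286) lay below Multi-Lin and above both HSCP clusters. Cpa3, a mast cell carboxypeptidase gene, was 15.4-fold lower, and Mcpt8, a basophil protease gene, 7.66-fold lower. In the fit over 12 clusters Mcpt8 did not pass (log2 fold change -0.45, edgeR adjusted p = 0.263), and most of its Multi-Lin counts came from 9.77% of female and 10.7% of male cells. Of 15 erythroid and megakaryocyte genes, 14 were lower and 1 did not pass, with Apoe 13.4-fold and Car2 11.3-fold lower. Of 14 stress and immediate early genes 13 were lower, Fos by 2.90-fold and Jun by 2.17-fold. Of 12 interferon response genes 10 were lower and 2 did not pass. Of 7 dendritic genes 6 were lower and 1 higher, but 4 were higher in the female library alone and 1 in the male. In the macrophage list 3 genes were higher and 5 lower, and Vcam1, an adhesion molecule gene, was 20.04-fold higher (54.5 ± 9.06 against 2.72 ± 0.550 CPM). Of 15 G2/M genes 12 were higher and 2 lower, and of 15 S-phase genes 9 were higher and 3 lower. The G2/M median log2 fold change of 0.34 was at percentile 92.65 of the random lists. The S-phase median of 0.17 was at percentile 32.2, so this list rose no more than genes of like expression. The mature neutrophil list had 5 higher and 2 lower of 10, and the lymphoid list 2 higher and 1 lower of 6. All list counts of this paragraph were the same when adjusted over the list alone.

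Across all genes tested, 8039 of 12051 passed edgeR's threshold, 3912 higher and 4127 lower in Gran. A difference of at least 2-fold was reached by 702 and 1678 of them. The largest increases under the naming rule besides Ly6c2 and Elane were Clec4a2 (17.5-fold), Nucb2 (10.9-fold) and Fcnb (10.8-fold). The largest decreases under the same rule were Csrp3 (30.5-fold), Prss34 (27.9-fold), Ms4a2 (22.8-fold), Ctla2a (22.5-fold) and Gata2 (21.1-fold). Prss34 did not pass in the fit over 12 clusters (log2 fold change -1.42). DESeq2 called 4893 genes on the same sums. With 4 sums the spread of each gene rested on 1 residual degree of freedom and on values shared between genes.

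**Figure D2:**
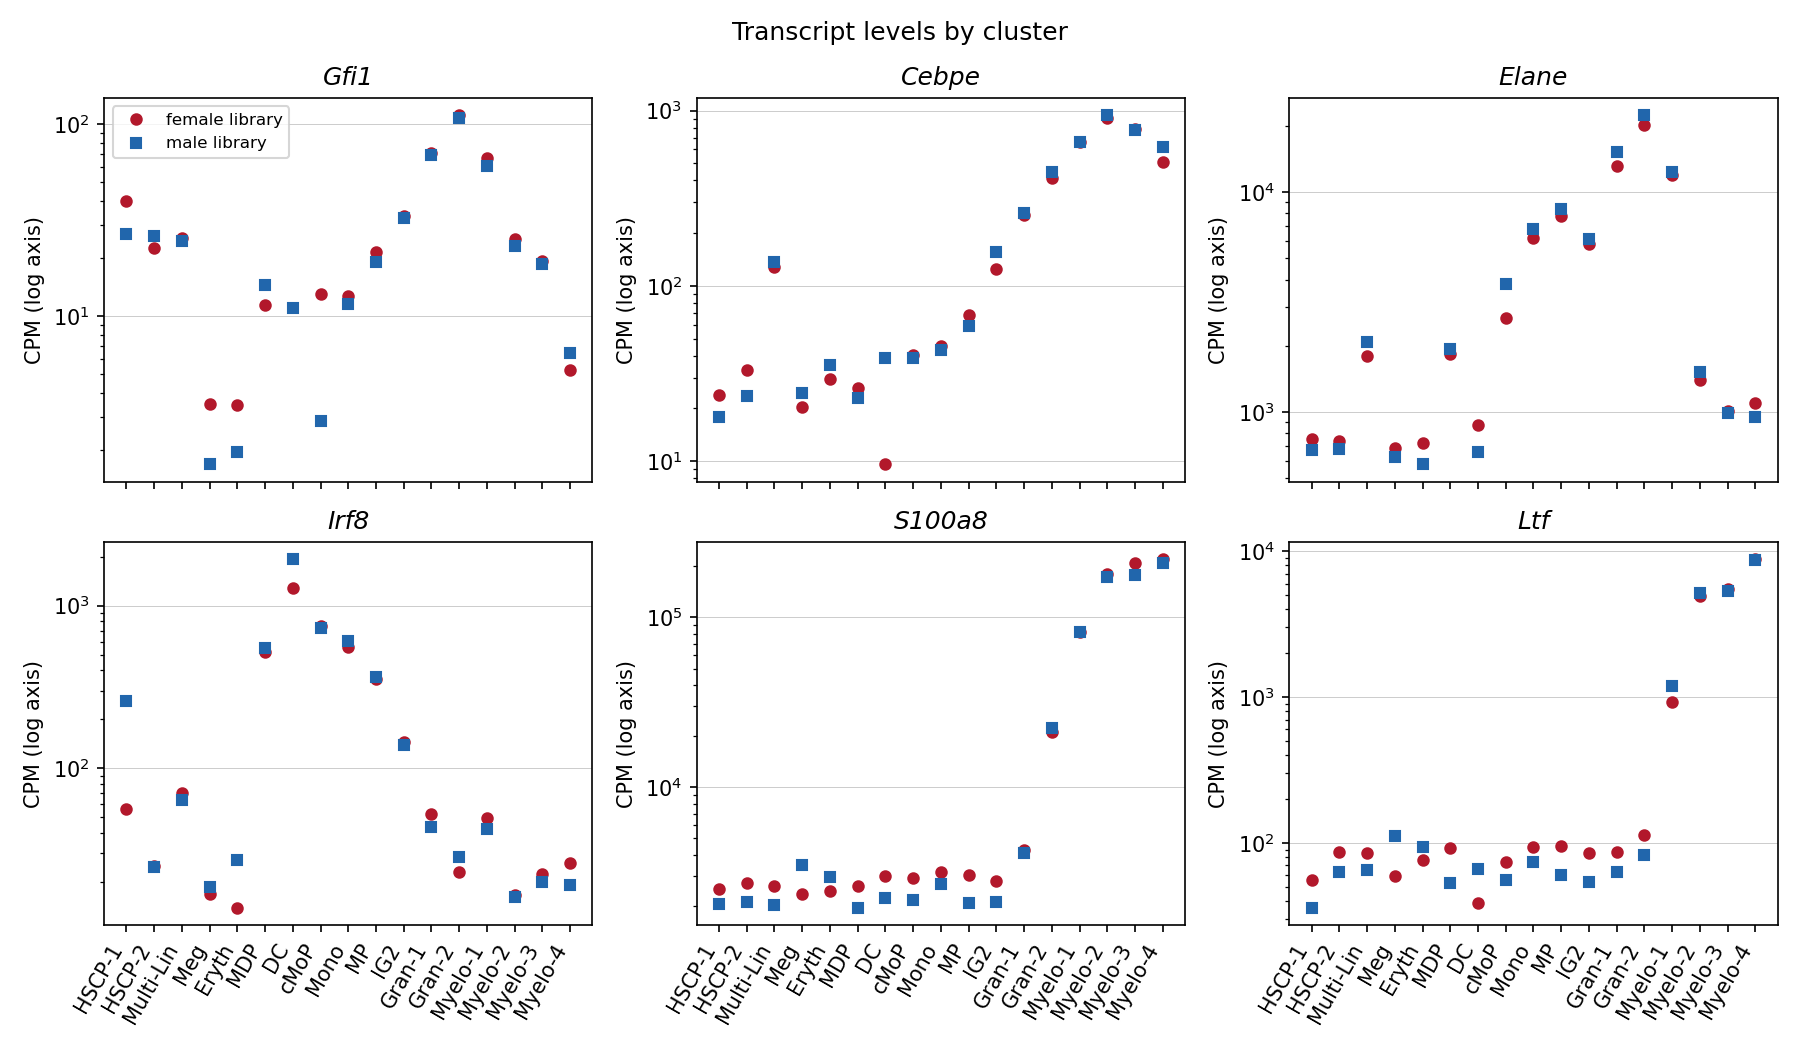
Transcript levels (CPM, log axis) of 6 genes in the 17 clusters, with circles for the female and squares for the male library; Gfi1 in female DC cells was 0 and is not drawn. Gfi1 was highest in Gran-2 (111 and 107 CPM), Irf8 in DC (1279 and 1929 CPM) and Ltf in Myelo-4 (8795 and 8704 CPM).

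The second comparison set the Gran against the monocytic clusters, the alternative branch of these progenitors. Irf8 was 13.4-fold lower in Gran (43.0 ± 2.54 against 572.4 ± 40.8 CPM) and Csf1r was 10.4-fold lower. Gfi1 was 7.06-fold higher (81.8 ± 0.737 against 11.6 ± 0.832 CPM) and Cebpe 7.76-fold higher (307.6 ± 12.4 against 39.7 ± 1.11 CPM). Primary granule genes were higher in Gran, with Elane at 3.04-fold, Ctsg at 2.49-fold, Prtn3 at 1.71-fold and Mpo at 1.67-fold.

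All 18 monocyte genes were lower in Gran (18 adjusted over the list alone), with a median log2 fold change of -3.51 at percentile 0 of the random lists. Psap, which encodes a lysosomal protein precursor, and Ms4a6c were 4.22-fold and 12.4-fold lower. Ly6c2 differed little (2948 ± 148 against 3283 ± 204 CPM, log2 fold change -0.15). Its sign turned with Gran-2 as the only Gran cluster (0.39) and in the fit over 12 clusters (0.82), and it did not pass without the library term. Of 12 primary granule genes 11 were higher and 1 lower, also over the list alone. Of 18 secondary granule genes 10 were higher and 4 lower (11 and 4 adjusted over the list alone). Their summed CPM was 9088 in Gran-1 and 37209 in Gran-2, against 6391 (MDP) to 9827 (cMoP) in the monocytic clusters. Most of the Gran-2 sum was S100a8. S100a8 was 3.26-fold higher, while Ngp differed by a log2 fold change of 0.10 and did not pass with DESeq2 or without the library term. Of 11 neutrophil regulators 6 were higher, 2 lower and 3 did not pass, the same over the list alone. Cebpa was 100.3 ± 6.90 CPM in Gran and 95.3 ± 6.16 in monocytic cells, which did not pass (edgeR adjusted p = 0.0838).

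Of 16 multipotent genes 7 were higher, 3 lower and 6 did not pass. Kit was 1.52-fold higher in Gran, and Cd34 and Sox4 were 2.92-fold and 2.18-fold lower. All 8 eosinophil, basophil and mast cell genes tested were higher in Gran, including Hdc, the histidine decarboxylase gene (4.31-fold), and Prg2 (11.5-fold). Of the Prg2 counts in Gran, 89.0% lay in 10 of 1187 female cells and 87.8% in 10 of 2139 male cells, so its fold rested on few cells. Few cells also held much of the Gran counts of Epx (72.1% in 2 female and 83.6% in 5 male cells). For Mcpt8, 19 female and 23 male Gran cells held 54.5% and 40.9%. For Hdc, 29 and 15 cells held only 8.48% and 3.41%. Of the 8 genes, 7 were higher in Gran in the female library alone and 8 in the male. Of 11 erythroid and megakaryocyte genes 6 were higher and 1 lower. All 14 stress and immediate early genes were lower, Fos by 2.22-fold and Jun by 1.28-fold, and Jun's log2 fold change was 0.07 with Gran-2 alone. Of 15 S-phase genes 2 were higher and 11 lower, and of 15 G2/M genes 2 were higher and 9 lower. Hmgb2, a G2/M list gene, fell by 0.11 on the log2 scale, was higher with Gran-2 alone (0.21), and did not pass without the library term. The mature neutrophil list had 5 higher and 3 lower of 10, the lymphoid list 4 and 2 of 6, the macrophage list 2 and 3 of 6, the dendritic list 2 and 2 of 7, and the interferon response list 4 and 3 of 11. All list counts past the threshold in this paragraph were the same when adjusted over the list alone. The libraries stood apart for the dendritic list. Of its 7 genes, 5 were higher in Gran in the female library (median log2 ratio 1.05) and 2 in the male (-0.85).

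In all, 5920 of 11602 genes passed edgeR's threshold, 2978 higher and 2942 lower in Gran. Of these, 594 and 762 differed by at least 2-fold, and with the Myelo clusters joined to Gran 896 were at least 2-fold higher. The largest increases among genes with a mean CPM of 50 or more, besides Cebpe, were Cd63 (12.1-fold), Prg2 on few cells, Pglyrp1 (6.74-fold) and Rgcc (6.67-fold). The largest decreases under the same limit, besides Irf8 and Ms4a6c, were Prdx4 (18.6-fold), Ly86 (13.6-fold) and Lgals3 (12.5-fold). DESeq2 called 2752 genes, a model without the library term 3660, and cells thinned to 5000 UMIs each 3203.

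**Figure D3:**
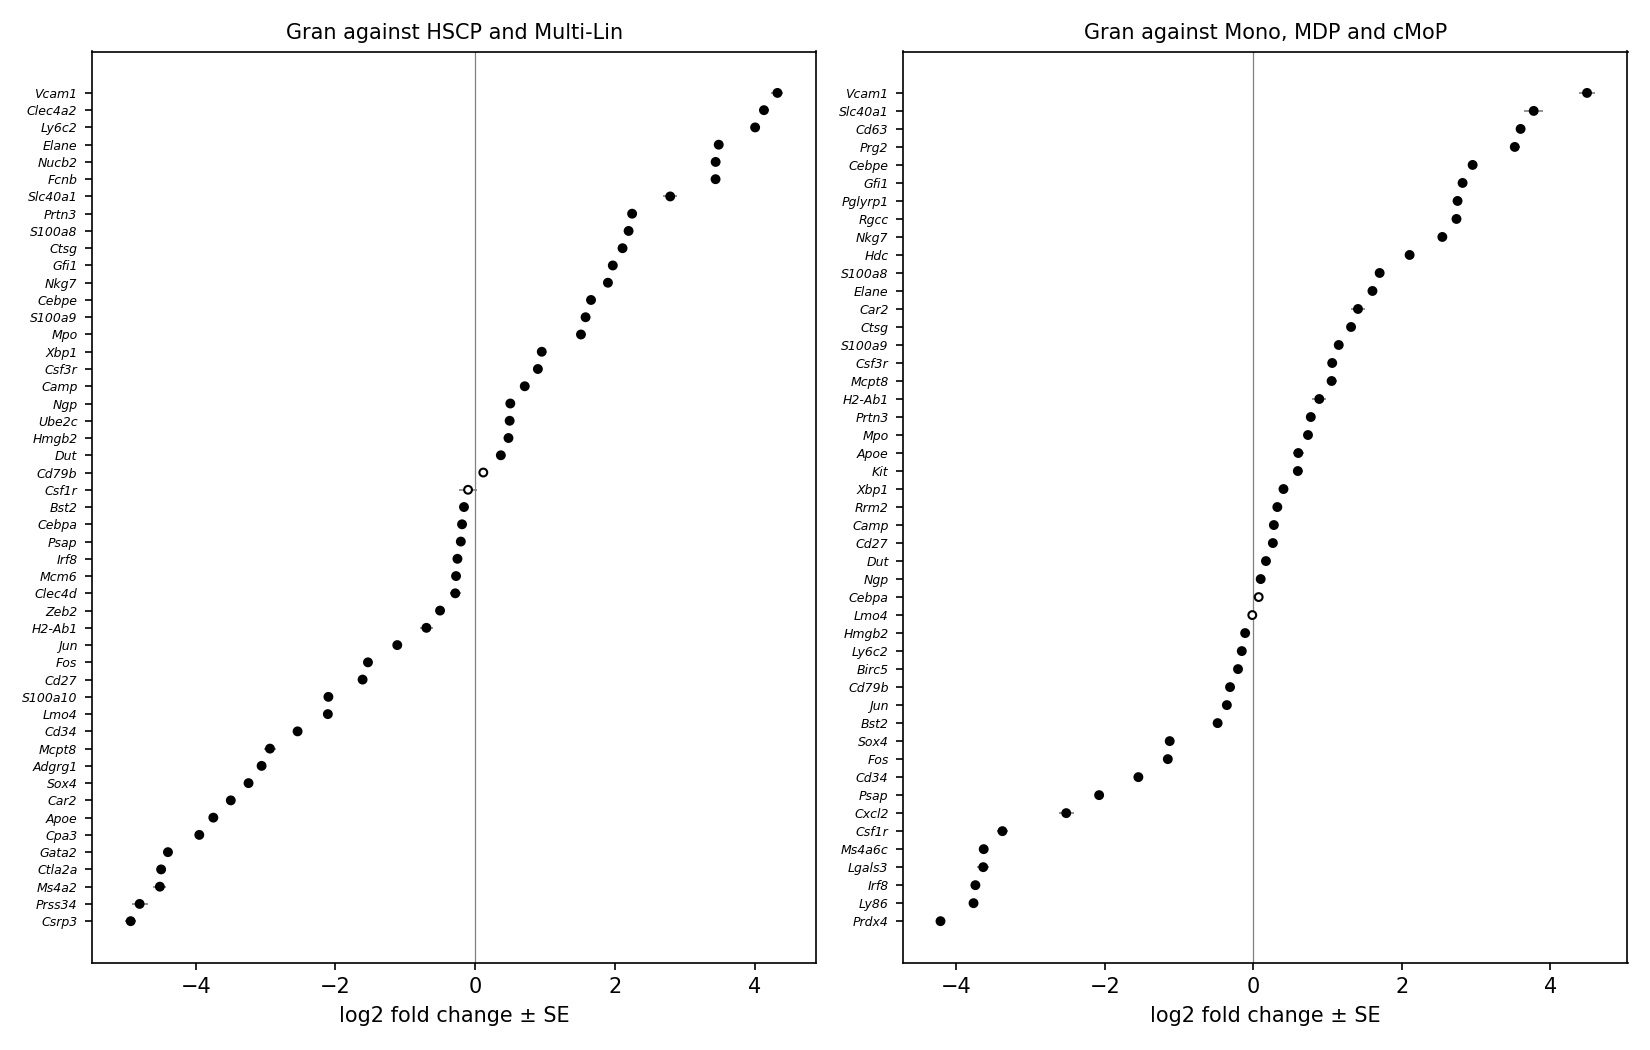
Log2 fold change (horizontal axis) of the genes chosen by the naming rule, Gran against the early clusters (left, 49 genes) and Gran against the monocytic clusters (right, 47 genes), with SE bars from edgeR. Filled points passed the adjusted threshold and open points did not. Elane lay at 3.48 on the left and 1.61 on the right.

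Surface proteins were compared across the same clusters by their antibody counts. Ly-6C counts were highest in Myelo-1 (median 26086.5 female, 15163 male), followed by cMoP (21762 and 10509). They were 13963 and 8689.5 in Gran-2, 13698.5 and 8779 in Myelo-2, 12083 and 6974.5 in Mono, and 860 and 700.5 in HSCP-2. CD11b, an integrin of myeloid cells, reached 6414 and 3239 in Myelo-2, 1277 and 712.5 in Gran-2 and 139 and 87 in Multi-Lin. Ly-6G, a neutrophil surface protein, was highest in Myelo-4 (14166 and 8183) and lay at 94 and 75 in Gran-1. CD117, the KIT receptor used for enrichment, was highest in Eryth in the female library (445, against 224 male) and in HSCP-2 in the male library (263, against 369.5 female). It was 40 and 31.5 in Myelo-4. In 1 male Myelo-3 cell the Ly-6G count was 4399311, and removal of duplicate reads from the antibody counts is not stated.

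**Figure D4:**
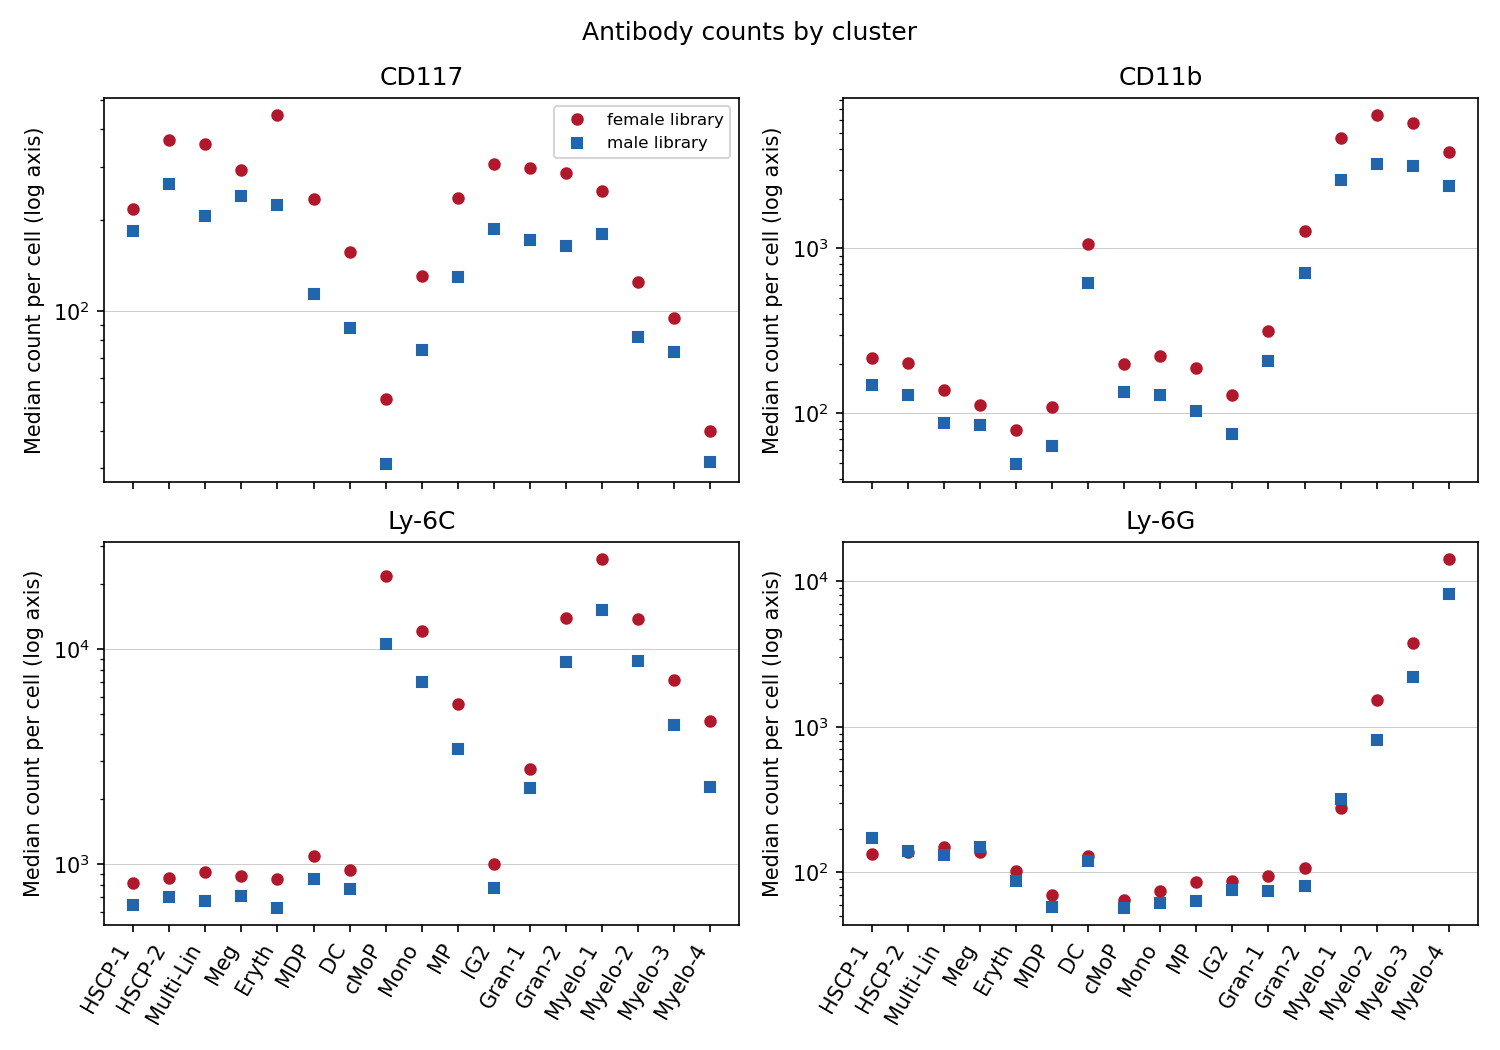
Median antibody count per cell (log axis) in the 17 clusters for the 4 antibodies, with circles for the female and squares for the male library. Ly-6G was highest in Myelo-4, at 14166 and 8183, and CD117 was lowest in Myelo-4 in the female (40) and in cMoP in the male library (31).

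On the deposited log share scale, the Gran class minus the early class gave -1.46 ± 3.47e-05 for CD117, -0.09 ± 0.03 for CD11b, 0.37 ± 0.03 for Ly-6C and -1.72 ± 0.09 for Ly-6G. The Gran class minus the monocytic class gave 1.33 ± 0.03 for CD117, 1.23 ± 0.04 for CD11b, -0.12 ± 0.003 for Ly-6C and 0.70 ± 0.08 for Ly-6G. Cells of both mRNA libraries gave the same sign in each of the 8 contrasts. Their antibody tags were sequenced as 1 pooled library, so the SD is not one between separate antibody libraries. How the tags of the 45 barcodes found in both mRNA libraries were divided was not examined. A share falls when another antibody of the cell rises, and 2 signs changed on other scales. CD11b in Gran against early was positive when centred within each cell (0.60) and as a ratio of median counts (2.99-fold). Ly-6G in Gran against monocytic was -0.08 when centred. Ly-6G counts were low in each of these classes. Their medians were 99 (female) and 77 (male) in Gran, 145 and 132.5 in early, and 74 and 61 in monocytic cells. Eryth had 102 and 88, and Myelo-4 had 14166 and 8183. Whether the class values exceeded background was not tested. By median counts the differences from early were smaller than by share for CD117 (0.796-fold against 0.233-fold) and Ly-6G (0.63-fold against 0.180-fold). For Ly-6C the difference from early was larger by median counts (5.21-fold against 1.44-fold). With 2 libraries an exact permutation test cannot go below p = 0.5, so no test was made.

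Across cells, each antibody count was set against the transcript of 1 gene paired with it beforehand. Ly-6C was paired with Ly6c2 only, and Ly6c1 was not included. Spearman's rho of Ly-6C with Ly6c2 was 0.737 ± 0.022 (SD, n = 2 libraries). It was 0.499 ± 0.0207 for Ly-6G with Ly6g, 0.496 ± 0.0225 for CD11b with Itgam and 0.279 ± 0.0477 for CD117 with Kit. Ly6c2 had a UMI in 97.8% of female and 96.5% of male cells, and the other 3 genes in 17.7% (Ly6g, male) to 46.9% (Kit, female). Cells tied at 0 limit rho for these 3, so the values do not rank how closely antibody and transcript go together. After thinning to 5000 UMIs the values were 0.719, 0.463, 0.348 and 0.140. CD117 counts had a rho of 0.333 (female) and 0.302 (male) with the total UMIs of the cell, above the values for Kit in the same libraries (0.313 and 0.245).

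The female and male libraries were set side by side to check the labels and to list the largest differences. Xist, the RNA that silences an X chromosome, was 914.2 CPM (908.06 to 920.5, exact Poisson 95% interval) in the female and 0.2001 CPM (0.129 to 0.295) in the male library. The Y-linked genes Ddx3y and Eif2s3y were 21.4 and 49.9 CPM in the male library, with 1 and 0 counts in the female. Kdm5d and Uty were 4.42 and 4.91 CPM in the male and had 0 counts in the female, which allows up to 0.0403 CPM at the upper 95% limit. Of 2266 genes with 50 CPM or more in a library, 98.8% lay within 0.5 on the log2 scale. Rpia, which encodes ribose-5-phosphate isomerase, was 87.3 CPM in the female and 26.3 CPM in the male library. Pf4, a platelet factor gene, was 96.0 and 44.5 CPM, and its log2 ratio of 1.11 was 0.53 with equal weight per cluster, with 9 of 17 clusters higher. Tsix, antisense to Xist, Rps2-ps6, a pseudogene whose counts are uncertain, and Hist1h2ap were also higher in the female library. Igkc was 74.4 CPM in the male and 0.0219 CPM in the female library, and 92.4% of its male counts came from 1 cell. Hspa1a (66.2 against 139.6 CPM), Cpa3 and Rsrp1 were lower in the female library, and higher in it in 0 of 17 clusters each. Prg2 was lower in the whole female library but higher in it in 9 of 17 clusters, and few cells held most of its counts in the Gran and early clusters. With 1 library per sex these differences have no replicate check.

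Gfi1 (ENSMUSG00000029275) lies on chromosome 5 from 107716655 to 107725805, Irf8 (ENSMUSG00000041515) on chromosome 8 from 120736358 to 120756694, Cebpe (ENSMUSG00000052435) on chromosome 14 from 54710363 to 54712174 and Elane (ENSMUSG00000020125) on chromosome 10 from 79886312 to 79888216. All are annotated as protein-coding genes in mm10, and the count table holds 1 value per gene, without position in the transcript.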

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

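No test between the libraries was made in this part, and the comparison of Myelo with Gran was chosen after the cluster names were seen. Genes chosen by the naming rule were looked at again where the female and male library changed in opposite directions. None of these differences was tested. In Gran against monocytic, Lmo4 had a log2 ratio of -0.047 in the female and 0.017 in the male library. In Myelo against Gran, Prg2 had -2.62 and 0.42, Sox4 -0.37 and 0.74, Cd34 -0.53 and 0.28, S100a10 -0.38 and 0.27, and Csf1r 0.086 and -0.14. Of these, Sox4 and Prg2 passed edgeR's threshold in the fit of both libraries, and neither passed with DESeq2 or with thinned cells. Prg2 rested on few cells: 10 Gran cells in each library held 89.0% and 87.8% of its Gran counts, and 3 male Myelo cells held 86.7% of its male Myelo counts.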

How the results depend on the processing

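Settings with Gran-2 alone, with Myelo joined to Gran, with median antibody counts, with log shares in the antibody correlations, and all settings of Myelo against Gran were added after seeing the data. Each library alone was also added for the antibodies. Most counts of genes and list members past the threshold stayed within 1.5 times. The exceptions were DESeq2 with 4893 (Gran against early), 2752 (Gran against monocytic, with 6 of the multipotent list) and 4986 (Myelo against Gran), and for Gran against monocytic 3660 without the library term and 3203 with thinned cells, which also tested fewer genes. The cause was not tested otherwise. Genes at least 2-fold higher in Gran than in monocytic clusters rose from 594 to 896 with Myelo joined to Gran. Genes at least 2-fold lower in Myelo than in Gran fell from 961 to 449 with Gran-2 alone. Shares of cells stayed within their intervals without the top 2% of cells, and the limit of 1000 UMIs removed no cell, so it is void.

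Centred within each cell, Gran minus early was -0.70 (CD117), 0.60 (CD11b, reversed), 1.09 (Ly-6C) and -0.96 (Ly-6G), and Gran minus monocytic 0.50, 0.50, -0.92 and -0.084 (Ly-6G, reversed). As a share of all counts of the class, CD117, CD11b and Ly-6C were -2.002, -0.55 and 0.43 against early, and CD117, CD11b, Ly-6C and Ly-6G were 0.99, 1.15, -0.076 and 0.83 against monocytic. By median counts the values were -0.23, 1.09 (CD11b, reversed), 1.65 and -0.46 against early, and 0.80, 0.91, -0.63 and 0.26 against monocytic. Without the top 2% of antibody counts CD117 was -1.43 and 1.28. The scales differ by construction. Thinned, rho was 0.140 (Kit), 0.348 (Itgam) and 0.463 (Ly6g); with log shares it was 0.362 (Itgam) and 0.359 (Ly6g). With 2 libraries each one lies within 1 SD of their mean by construction, so leaving one out says nothing about the stability of the antibody values or of rho.

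Single genes with reversed sign, cause not tested, were as follows on the log2 scale. With Gran-2 alone against monocytic: Cd27 -0.77, Birc5 0.030, Jun 0.070, Hmgb2 0.21, Lmo4 0.26 and Ly6c2 0.39. With Myelo against Gran-2 alone: Csf3r -0.088, Vcam1 -0.70, Prg2 0.077, Cd27 0.50, Csf1r 0.50, Irf8 0.57, S100a10 1.01 and Cd34 1.28. With Myelo joined to Gran: Cd79b -0.068 against early, and Cebpa -0.14, Birc5 0.16, Hmgb2 0.45 and Lmo4 0.93 against monocytic. In the fit over 12 clusters, which changes several choices together: Irf8 0.16, Cebpa 0.77 and Csf1r 0.94 against early; Cd27 -0.55, Hmgb2 0.10, Lmo4 0.10 and Ly6c2 0.82 against monocytic; Vcam1 -0.13, Csf1r 0.10, S100a10 0.27 and Cd34 0.35 for Myelo against Gran. Thinned cells gave Lmo4 0.071 against monocytic. Lmo4 was 0.0044 without a filter and 0.0017 without the top 2% of cells. For Myelo against Gran, each library alone gave -2.62 to 0.42 for Prg2 and -0.37 to 0.74 for Sox4. Without a change of sign, 39 values of single genes no longer passed and 8 newly passed.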

Other observations

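The comparison of Myelo with Gran clusters was added after the cluster names were seen, and all tests below were chosen after the result was seen, except the one on genes near Rpia. The Myelo clusters carried the secondary granule genes: all 18 were higher than in Gran (18 adjusted over the list alone), with a median log2 fold change of 5.40 at percentile 100 of the random lists. Camp was 71.5-fold and Ngp 78.1-fold higher, and Ifitm6 and Ly6g 101-fold and 67.2-fold. Of 12 primary granule genes 10 were lower, Ctsg by 3.94-fold and Elane by 2.15-fold. These folds pool unlike clusters. Summed primary granule CPM, unscaled, was 31114 in Myelo-1 and 4739 to 5955 in Myelo-2 to Myelo-4, against 45366.5 (Gran-1) and 57750 (Gran-2). Gfi1 was 1.53-fold lower in Myelo, and Cebpe was 3.65-fold higher (927.0 ± 39.7 against 253.9 ± 12.1 CPM). All 15 G2/M genes were higher, Ube2c by 3.27-fold, and 4 of 15 S-phase genes were higher and 9 lower. The G2/M rise did not extend to Myelo-4. Summed G2/M CPM, unscaled, was 4248, 6280, 5193 and 1375 in Myelo-1 to Myelo-4, against 2525 in Gran-1 and 3045 in Gran-2. More genes were higher than lower in the macrophage (8 and 0 of 9), erythroid and megakaryocyte (12 and 0 of 13), stress and immediate early (11 and 2 of 14) and multipotent (11 and 3 of 16) lists. The same held for the mature neutrophil (8 and 1 of 10), interferon response (6 and 2 of 11), regulator (6 and 3 of 11), dendritic (4 and 2 of 7) and eosinophil, basophil and mast cell (4 and 3 of 10) lists. The monocyte (4 and 7 of 16) and lymphoid (1 and 5 of 6) lists had more lower genes. Summed erythroid and megakaryocyte CPM was low, at 75.1 in Gran-1, 55.6 in Gran-2 and 56.3 (Myelo-2) to 183 (Myelo-3) in Myelo. Summed macrophage CPM was 48.9 in Gran-1 and 167 in Gran-2, against 178, 105, 109 and 82.3 in Myelo-1 to Myelo-4. Summed interferon response CPM was 143 in Gran-1 and 96.8 in Gran-2, against 103, 63.7, 87.8 and 219 in Myelo-1 to Myelo-4. For the mature neutrophil list it was 93.1 and 123, against 181, 207, 327 and 4912, and Myelo-4 held 59 cells. These sums are unscaled. The TMM factors, 1.21 and 1.17 for Gran and 0.822 and 0.862 for Myelo (female, male), raise each Myelo ratio. The libraries stood apart for the multipotent list, with 7 of 16 genes higher in Myelo in the female and 13 in the male library. In the female library 4 of the 16 lay within 0.05 of 0 on the log2 scale, and the difference between the libraries was not tested. Of the 13 erythroid and megakaryocyte genes, 13 were higher in the female and 12 in the male library. In all, 3847 genes were higher and 3726 lower of 11473 tested by edgeR. DESeq2 called 4986.

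Some genes were singled out in small clusters after their values were seen. Myelo-4 had Mmp8 at 1118 CPM in the female and 1116 CPM in the male library, and Retnlg at 3645 and 4240 CPM. Dntt, a lymphoid gene, was 798.3 and 741.4 CPM in HSCP-1, a cluster of 24 cells. Cd74 was 31766 and 25818 CPM in DC, Pf4 5354 and 3596 CPM in Meg, and Car1 2459 and 2278 CPM in Eryth. In Multi-Lin, 9.77% of female cells (95% interval 7.65% to 12.2%) and 10.7% of male cells (8.90% to 12.7%) held 10 or more Mcpt8 UMIs. These cells held 92.0% and 91.6% of the cluster's Mcpt8 counts. Outside Multi-Lin the shares were 0.849% and 1.01%, at higher median depth (22246.5 and 19519.5 against 17137.5 and 13805 UMIs).

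S100a8, S100a9, Camp and Ngp were counted in each early, Meg, Eryth and MDP cluster. Free RNA from Myelo-like cells may contribute: 35 of 36 ratios to S100a8 lay within 1.5 times of the Myelo ratio. The exception, Camp in male HSCP-1 (50 counts), was 1.67 times apart and broke the bound as first written, but its counting interval, added after that result, reached the bound, so this explanation stays open. In DC, cMoP, Mono, MP and IG2 all such ratios also lay within 1.5 times of the Myelo ratio. They ran from 0.809 (Camp, male cMoP) to 1.22 (S100a9, female DC). Mono, MDP and cMoP form the monocytic class, so the question is open for that class as well. Doublets with Myelo cells as the whole source are argued against in HSCP-2, Multi-Lin, Eryth and MDP, where the top 5% of cells held at most 23.5% of S100a8 counts, and in Meg, where they held 32.1% but the median cell had at least 61.9% of the mean S100a8 CPM in each library; a smaller part from doublets stays open. In Gran-2 the Camp to S100a8 ratio was at most 0.214 of that in Myelo, which argues against free RNA as the whole source there.

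In 1 male Myelo-3 cell the Ly-6G count was 4399311. A 10-base tag has 1048576 different forms, so the counts cannot be distinct tags of that length in every cell; the tag length is that of the v2 assay and is not in the labels. Counting of duplicate reads in all cells is a candidate explanation that these values leave open. The antibody counts sum to 79.99% of the 152 M antibody reads that the labels imply. Distinct tags with few duplicate reads would also give a sum near the reads, so the sum cannot tell these apart. No biological explanation was tested.

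Igkc in the male library rested on 1 cell in Gran-2, with 8597 Igkc, 1680 Jchain and 841 Ighm counts, or 92.4% of the library's Igkc. It had 19 Elane counts against a Gran-2 median of 426.5. A candidate source is 1 cell of another type, rich in immunoglobulin transcripts, that was placed in Gran-2; no list of markers had been fixed for it, so its type is not named. The other 703 Igkc counts lay in 666 cells, with a Jchain to Igkc ratio 0.852 times that in the cell, which is consistent with free RNA of like origin. A difference between the sexes cannot be told apart from the library, with 1 library per sex.

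A gain of gene copies around Rpia was considered for its higher female level. The 10 nearest genes with over 5 CPM in both libraries had a median log2 female to male ratio of -0.015 (from -0.12 to 0.31), which argues against a gain that spans them. All 10 lie at higher coordinates than Rpia, and the nearest is 505957 bases away from start to start, so a smaller gain, or one on the other side, may remain.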
